A study of Mus musculus with 15 samples.

How the data were processed

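Messenger RNA was measured in 15 samples of mouse CD4 T cells, 5 in each of 3 conditions named Th1, Th17 and Tfh (T follicular helper). Per the labels' protocols, naive cells were stimulated for 3.5 days with plate-bound antibodies against CD3 and CD28, then sorted by flow cytometry into Trizol LS. The cells carried altered Ifng and Il17a alleles, which by their allele names are cytokine reporters. The design text gives the sort of the Th1 cells as positive for interferon gamma and that of the Tfh cells as CXCR5 positive and IL-17A negative. The gate of the Th17 cells and the cytokines added to each culture are not given in the sources used here. Libraries were made from 100 ng of RNA with the Lexogen SENSE kit, per the labels.

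The deposited values are raw read counts per gene, listed by Entrez gene ID for 27179 genes. Per the submitters' processing notes, reads were aligned with STAR 2.7.2b to the mm10 mouse genome and counted with featureCounts 1.6.4. The gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here. Values of genes with near-identical copies, or that overlap other genes, are therefore uncertain. All 15 files of single samples held the same counts as the columns of the series table. Gene names came from a RefSeq table of the GRCm38.p6 assembly for 25262 IDs and from a GENCODE annotation for 31, and 1886 IDs had no name. Named genes carried 98.2% of all counts. Coordinates are those of the RefSeq table on GRCm38, the assembly that mm10 denotes.

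Each condition's 5 libraries were treated as replicates. No label says whether they came from separate mice or cultures, so p-values measure the spread between these samples, which may be technical. The lowest chi-square per gene between any pair of libraries in a condition was 9.80, so no pair agreed within counting noise.

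Genes were tested in R 4.3.3 with edgeR 4.0.16. The default filter on low counts on the 3 conditions left 12591 genes and removed 5472 others that had a count. Library sizes were scaled with TMM factors, 1 model without covariates was fitted to all 15 libraries, and each comparison used the quasi-likelihood test with robust spread estimates. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Levels are CPM, counts scaled to 1 M per library (M for a 1 followed by 6 zeros) on the TMM-scaled library sizes, as mean ± SD of 5 libraries. Errors of log2 fold changes are standard errors from the F statistic. Where all libraries of a condition had a count of 0, the fold is a lower bound against a floor of 3 counts over the condition. With 1 to 3 counts, the ratio of summed counts is given with its exact (Clopper-Pearson) 95% interval. In single libraries, 3 counts correspond to 0.119 CPM in the deepest and 0.616 CPM in the shallowest. Bounds and intervals cover counting error only, since reads amplified by PCR are not independent molecules.

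The genes to be named were fixed by a rule before the data were examined. It took 11 genes in every comparison (among them Tbx21, Bcl6, Maf, Foxp3, Gata3, Prdm1, Ifng, Il17a, Il21 and Cxcr5) and, from each lineage list, up to 4 members per direction with the largest fold changes. It added up to 2 members of every other list, the 4 highest and 4 lowest fold changes over all genes, and the 4 genes most set apart in each condition and direction. Apart from the 11, a gene had to pass the test, have no overlap between the libraries of the compared conditions, and reach a mean of 10 CPM in the higher one. Names made only of an identifier, names ending in Rik and predicted genes starting with Gm were left out of the extremes. Other genes named were chosen after their values were seen, and the text says so.

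Also fixed before the data were examined were 28 gene lists. They cover the Tfh, Th17, Th1, Treg and Th2 programmes, TGF-beta, STAT3, IL-2 and STAT5, and interferon responses, naive and lymph-node homing genes, co-inhibitory receptors, cytotoxic effectors, cytokines, chemokine receptors, and AP-1, NFAT and NR4A factors. Further lists cover proliferation, glycolysis, cholesterol synthesis, the integrated stress response, heat shock, the p53 response, mitochondrially encoded genes, and markers of B cells, myeloid and dendritic cells, CD8 T cells, NK and other innate lymphocytes, gamma-delta T cells and erythroid cells. Ifng, Il17a and Cxcr5, on which the sorts acted, belong to the Th1, Th17 and Tfh lists. Ifng and Il17a are also on the cytokine list, and Cxcr5 is on the chemokine receptor list. Calls of these lists thus rest in part on sorted genes. The members Tcrg-C1, Tcrg-C2 and Tcrg-C4 of the gamma-delta list and Hbb-bt of the erythroid list matched no gene name and were not tested. No erythroid gene passed the filter on low counts, which left 27 lists. Each list was tested against all other genes with camera in limma 3.58.1, two-sided, at a preset correlation between genes of 0.01, with adjustment over the 27 lists of a comparison. The test was repeated with a correlation estimated from the residuals. At the preset correlation, groups of mixed conditions also gave up to 11 (Tfh against Th1), 12 (Tfh against Th17) and 13 (Th17 against Th1) lists, so the number of lists called means little.

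The same code was tested on counts simulated for 12591 genes from the real means and library sizes. In each comparison only 67, 67 and 66 genes were changed, by 1.5-fold, 2-fold and 4-fold, and a single set of counts was drawn. The real comparisons called 16.8% to 49.3% of genes. Recovery and false calls depend on that share, so the simulated values are not those of the real comparisons. For Tfh against Th17, the code recovered 17.9% of genes changed 1.5-fold, 56.7% of those changed 2-fold and 86.4% of those changed 4-fold. Of its calls, 5.3% were false. For Tfh against Th1 the shares were 11.9%, 53.7% and 89.4%, with 2.8% false calls. For Th17 against Th1 they were 10.4%, 53.7% and 78.8%, with no false call.

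Alternatives fixed in advance were RLE size factors, library size only, no filter on low counts, a strict filter of 10 CPM in 5 libraries, DESeq2 1.42.0, limma-voom with quality weights, glmTreat for fold changes above 2-fold, only the 2 conditions compared, each library left out in turn, and the replicate number as a block. For lists, fry was also run. A correction for each library's trend with transcript GC content, that correction together with the replicate block, and a fit without the 5 libraries of steepest GC trend were added after seeing the data. GC content was known for 91.6% of the genes tested.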

Results

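RNA sequencing compared 3 kinds of mouse CD4 T cells after 3.5 days of stimulation in culture, with 5 libraries each. Th1 cells make interferon gamma, Th17 cells make the IL-17 cytokines, and Tfh cells carry the chemokine receptor CXCR5 and help B cells. The series concerns the choice between the Tfh and Th17 fates, its dependence on TGF-β, and the part played in it by c-Maf, the transcription factor encoded by Maf. Total counts ran from 4.87 M in Tfh replicate 1 to 25.2 M in Th1 replicate 3, with a median of 10.5 M. By condition they were 13.1 ± 6.95 M in Th1, 10.4 ± 1.12 M in Th17 and 8.77 ± 2.81 M in Tfh (SD, n = 5).

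The first principal component held 58% of the variance of log2 CPM and placed Th1 libraries between -105.4 and -100.9, Th17 libraries between 32.7 and 37.9, and Tfh libraries between 62.6 and 81.4. Across genes, the median correlation between libraries was 0.962 within Th1, 0.966 within Th17 and 0.957 within Tfh. It was 0.936 between Th17 and Tfh, 0.845 between Th1 and Th17 and 0.793 between Th1 and Tfh. Genes are not independent replicates, so these values only describe the libraries. Tfh replicate 1, the shallowest library, lay at 94.0 on the second component, against -1 to 12.1 for the other Tfh libraries. Within conditions, libraries differed in how their levels followed transcript GC content, with Spearman's rho across genes from -0.79 to 0.81. Across the fold changes of the 3 comparisons that rho was 0.03, 0.03 and 0.00.

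**Figure D1:**
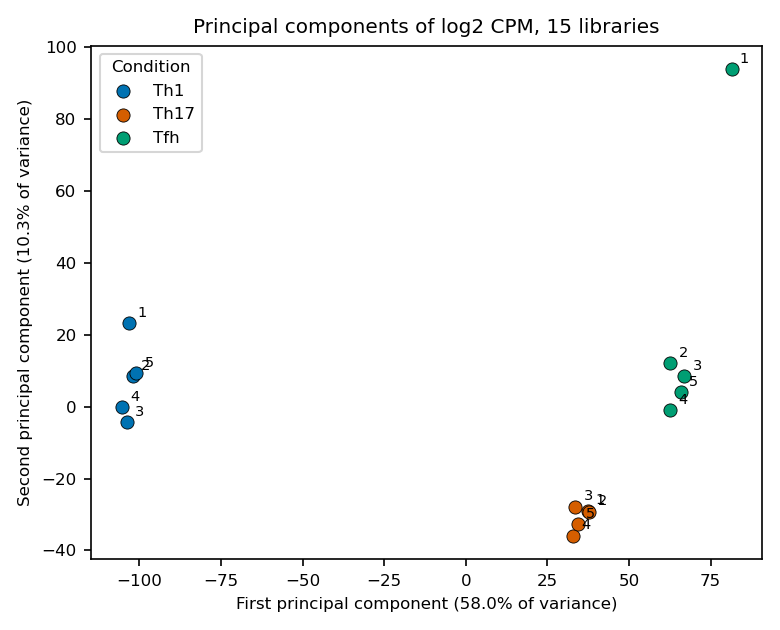
Each point is a library, coloured by condition and numbered by replicate, placed by its scores on the first 2 principal components of log2 CPM (58% and 10.3% of the variance). Th1 libraries lie at -105.4 to -100.9 on the horizontal axis and Th17 and Tfh libraries at 32.7 to 81.4, and Tfh replicate 1 stands apart at 94.0 on the vertical axis.

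The genes on which the sorts acted followed the labels, which is no finding. Ifng (gene ID 15978; chromosome 10, 118441046 to 118445894) was at 840 ± 136 CPM in Th1, 0.510 ± 0.322 in Th17 and 0.341 ± 0.295 in Tfh libraries (SD, n = 5 here and below). Il17a (16171; chromosome 1, 20730905 to 20734496) was at 225 ± 24.4 CPM in Th17, 15.1 ± 6.18 in Tfh and 0.0595 ± 0.0829 in Th1. Cxcr5 (12145; chromosome 9, 44511787 to 44526444) was at 169 ± 14.2 CPM in Tfh, 39.0 ± 4.75 in Th17 and 10.3 ± 2.13 in Th1.

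Among the regulators, Maf (17132; chromosome 8, 115703253 to 115706894) reached 1630 ± 350 CPM in Tfh and 798 ± 194 in Th17, with 10.7 ± 2.75 in Th1. Bcl6 (12053; chromosome 16, 23965050 to 23988866), the repressor that specifies Tfh cells, was at 125 ± 40.2 CPM in Tfh, 59.2 ± 18.7 in Th17 and 13.3 ± 4.71 in Th1. Tbx21 (57765; chromosome 11, 97098007 to 97115331), which encodes the Th1 factor T-bet, was at 181 ± 58.0 CPM in Th1, 3.77 ± 0.834 in Tfh and 2.55 ± 1.08 in Th17. Prdm1 (12142; chromosome 10, 44437174 to 44528558), whose product Blimp-1 opposes Bcl6, was at 26.0 ± 2.50 CPM in Th1, 0.574 ± 0.394 in Th17 and 0.115 ± 0.215 in Tfh. Gata3 (14462; chromosome 2, 9857078 to 9887953), the Th2 factor, was at 24.4 ± 2.82 CPM in Tfh, 6.82 ± 1.45 in Th17 and 7.39 ± 3.40 in Th1. Foxp3 (20371; chromosome X, 7579676 to 7595243), the regulatory T cell factor, was at 13.0 ± 4.57 CPM in Tfh, 7.20 ± 2.26 in Th17 and 0.483 ± 0.669 in Th1. Il21 (60505; chromosome 3, 37222759 to 37232636), a cytokine of Tfh and Th17 cells, was at 981 ± 178 CPM in Tfh, 922 ± 167 in Th17 and 96.1 ± 26.5 in Th1.

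**Figure D2:**
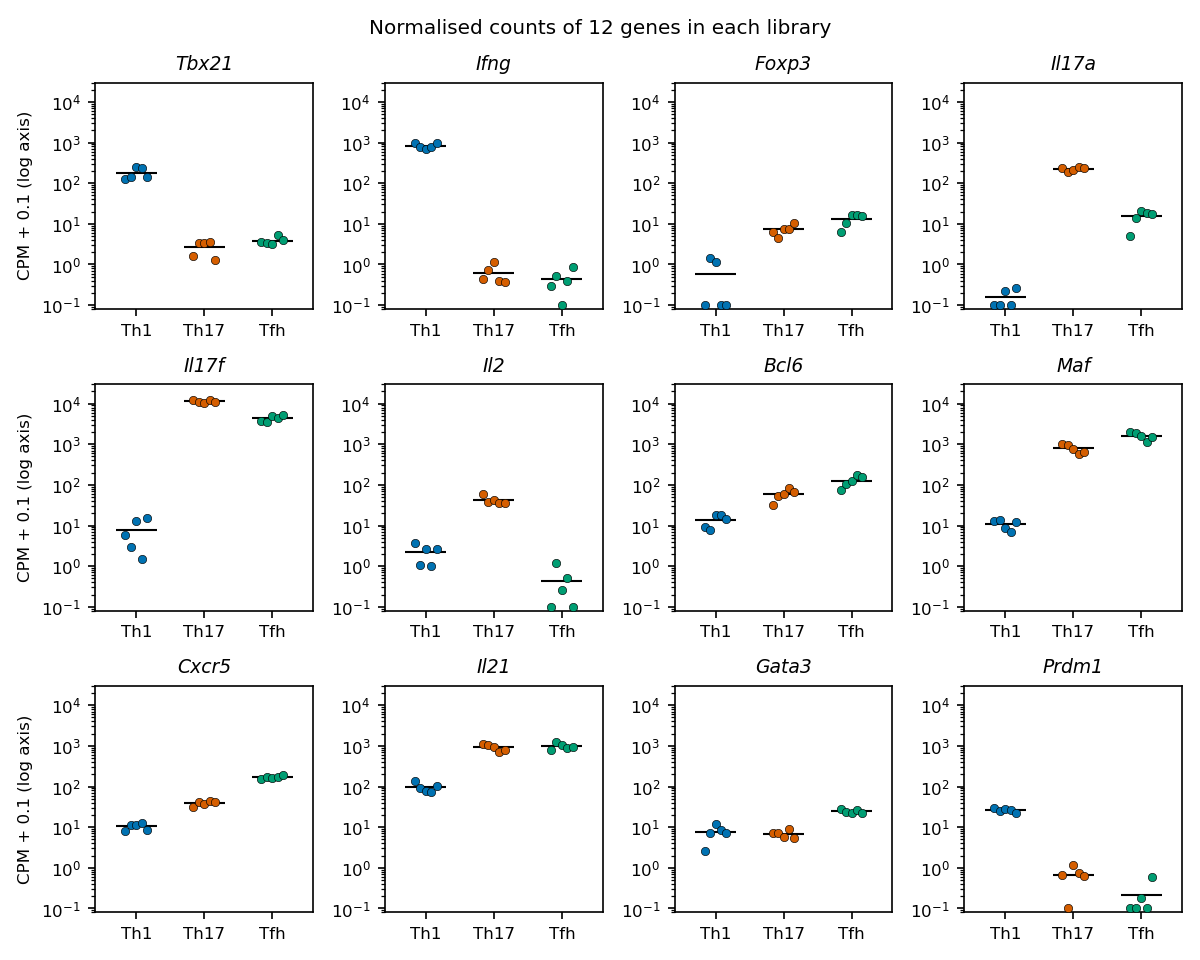
Each panel shows 1 gene in the 15 libraries as CPM + 0.1 on a log axis, with a point per library and a line at the mean of each condition. Il21 lies at like levels in Th17 and Tfh libraries (means of 922 and 981 CPM), while Il2 has means of 42.2 CPM in Th17 and 0.338 CPM in Tfh.

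The comparison of Tfh with Th17 cells addresses how the 2 sorted populations differ. The Tfh gate left out IL-17A positive cells, so genes expressed together with Il17a may differ through the gate. Fate and gate cannot be told apart here. Tfh cells held 2.04-fold more Maf than Th17 cells (log2 fold change 1.03 ± 0.20, SE, n = 5 per condition, edgeR adjusted p = 0.00125) and 2.11-fold more Bcl6 (1.08 ± 0.27, edgeR adjusted p = 0.0104), although the Bcl6 values of the libraries overlapped. Il21 differed by less than its error (0.09 ± 0.18). The cytokine genes parted more. Il2, the T cell growth factor, fell 127-fold from 42.2 ± 10.1 CPM in Th17 (-6.99 ± 0.55, edgeR adjusted p = 1.97e-07; -7.94 without Tfh replicate 2), whereas Il17f fell 2.54-fold and stayed at 4430 ± 755 CPM in Tfh cells sorted as IL-17A negative, against 11300 ± 727 CPM in Th17 (-1.34 ± 0.36, edgeR adjusted p = 0.0142).

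Of the 20 Tfh programme genes tested, 7 rose, 2 fell and 11 did not pass (12 and 2 adjusted over the list alone), with a median log2 fold change of 0.52 (camera adjusted p = 0.000834). Besides Cxcr5, those that rose included Tcf7, which encodes the factor TCF-1 (2.71-fold, 1.44 ± 0.22), and the DNA-binding factors Tox (2.38-fold, 1.25 ± 0.21) and Tox2 (3.12-fold, 1.64 ± 0.30). The 2 that fell were Cd40lg, which encodes the CD40 ligand that activates B cells (3.42-fold, -1.78 ± 0.15), and Cd200 (2.04-fold, -1.03 ± 0.14). Gata3 rose 3.57-fold (1.84 ± 0.29). Foxp3 (0.86 ± 0.54), Tbx21 (0.57 ± 0.30) and Ifng (-0.60 ± 0.56; -1.28 without Tfh replicate 5, edgeR adjusted p = 0.194) did not pass, except Foxp3 with limma-voom (adjusted p = 0.0124). Prdm1, with 6 counts in Tfh and 31 in Th17, did not pass either (-2.05 ± 0.76, edgeR adjusted p = 0.0738), but passed without Tfh replicate 5 (-3.88, edgeR adjusted p = 0.00900) and without Th17 replicate 2 (-2.35, edgeR adjusted p = 0.0177). It also passed with DESeq2 (adjusted p = 0.0156), with the GC correction chosen after seeing the data (edgeR adjusted p = 0.0493), and with that and a replicate block (edgeR adjusted p = 0.0497).

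In the Th17 programme, 10 of 21 genes fell, 3 rose and 8 did not pass (13 and 3 adjusted over the list alone), with a median of -0.78 (camera adjusted p = 0.00338). Il17a, on which the Tfh gate acted, fell 14.7-fold (-3.88 ± 0.28). The chemokine gene Ccl20 fell 4.56-fold (-2.19 ± 0.29) and the receptor gene Il23r 4.29-fold (-2.10 ± 0.32). Il1r1 rose 1.84-fold (0.88 ± 0.15), and Ahr, a ligand-activated factor, rose 1.61-fold (0.69 ± 0.13). Among the 23 cytokine genes, 10 fell, 1 rose and 12 did not pass (11 and 2 adjusted over the list alone), with a median of -0.97 (camera adjusted p = 1.40e-05). In the Th1 programme 9 of 23 genes fell, none rose and 14 did not pass (9 and 0 adjusted over the list alone), with a median of -0.60. Its camera adjusted p was 0.000965, but the adjusted p = 0.0726 with an estimated correlation. Ccl3 fell 14.9-fold (-3.89 ± 0.36) and Ccl4 5.09-fold (-2.35 ± 0.27), both chemokine genes, and Bhlhe40 fell 2.83-fold (-1.50 ± 0.14).

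Genes of growth and metabolism were lower in Tfh than in Th17 cells. Of 24 proliferation genes, 22 fell and 2 did not pass (24 fell adjusted over the list alone), with a median of -1.10 (camera adjusted p = 7.80e-16). Bub1, of the spindle checkpoint, fell 2.6-fold (-1.38 ± 0.23). In glycolysis 14 of 19 fell and 5 did not pass (15 fell adjusted over the list alone), with a median of -1.07 (camera adjusted p = 2.51e-11). Hexokinase gene Hk2 fell 4.32-fold (-2.11 ± 0.18) and glucose transporter gene Slc2a3 3.86-fold (-1.95 ± 0.26). Cholesterol synthesis showed 15 of 22 genes lower and 7 not passing (19 lower adjusted over the list alone), with a median of -0.85 (camera adjusted p = 1.75e-11), and Lss fell 3.09-fold (-1.63 ± 0.20). IL-2 and STAT5 response genes fell in 9 of 15 cases and 6 did not pass (10 fell adjusted over the list alone), with a median of -0.79 (camera adjusted p = 1.58e-06), and the cytokine gene Lta fell 4.07-fold (-2.03 ± 0.22). Heat shock genes fell in 5 of 8 cases and 3 did not pass (5 fell adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.00325, but 0.0530 with the strict filter on low counts), and Hspe1 fell 1.68-fold (-0.75 ± 0.16). Naive and lymph-node homing genes rose in 6 of 12 cases and 6 did not pass (6 rose adjusted over the list alone), with a median of 0.35 (camera adjusted p = 0.00160). They included Klf2, a factor of naive T cells, which rose 3.81-fold (1.93 ± 0.22).

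For 2 further lists the call was lost with an estimated correlation. The integrated stress response had 9 of 15 genes fall, 2 rise and 4 not pass (9 and 2 adjusted over the list alone), with a median of -0.70 (camera adjusted p = 0.00173, and adjusted p = 0.0695 with an estimated correlation). Phgdh, of serine synthesis, fell 2.17-fold (-1.12 ± 0.27), and Ddit3, which encodes the stress factor CHOP, rose 1.79-fold (0.84 ± 0.17). The TGF-beta response had 6 of 21 genes rise, 3 fall and 12 not pass (10 and 3 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 0.0481, and adjusted p = 0.230 with an estimated correlation). The integrin gene Itgae rose 5.07-fold (2.34 ± 0.23). The camera call of the TGF-beta list was lost without any of 8 single libraries: adjusted p = 0.0529 without Th1 replicate 4, 0.0688, 0.0574, 0.0622 and 0.0553 without Th17 replicates 1, 2, 3 and 5, and 0.0523, 0.101 and 0.0886 without Tfh replicates 3, 4 and 5. It was also lost with RLE factors (0.0526), library size only (0.0532), the strict filter (0.0574), the replicate block (0.0545) and the GC correction (0.0640).

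The remaining lists were not called between Tfh and Th17. STAT3 response genes (4 rose, 3 fell and 8 did not pass, 4 and 4 adjusted over the list alone) included Il6st, which encodes the IL-6 receptor subunit gp130 and rose 2.85-fold (1.51 ± 0.13), and Il10, which rose 2.22-fold (1.15 ± 0.29). Interferon response genes (2 rose, 6 fell, 16 did not pass, 3 and 7 adjusted over the list alone; median -0.11, or -0.09 with bounds) included Gbp2, lower by 2.85-fold (-1.51 ± 0.18). Chemokine receptors (3 rose, 4 fell, 6 did not pass, 3 and 4 adjusted over the list alone) included Cx3cr1, higher by 5.17-fold (2.37 ± 0.42). Co-inhibitory receptors (3 rose, 1 fell, 5 did not pass, 3 and 1 adjusted over the list alone) included Lag3, higher by 2.22-fold (1.15 ± 0.26). AP-1, NFAT and NR4A factors had 3 rise and 3 fall of 18 (3 and 3 adjusted over the list alone), Treg genes 4 and 3 of 14 (4 and 5 adjusted over the list alone), Th2 genes 2 and 3 of 8 (2 and 3 adjusted over the list alone), cytotoxic genes 1 and 2 of 9 (1 and 2 adjusted over the list alone), and p53 genes 3 and 1 of 10 (3 and 1 adjusted over the list alone). The p53 list had a median of 0.12, or 0.23 with bounds for genes without counts, and a mean of -0.02. The Treg list had a median of 0.00 and a mean of 0.10. None of the 8 mitochondrially encoded genes passed in edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05), DESeq2 or limma-voom. Among markers of other cells, few of which had counts, 1 rose and 1 fell of 3 B cell genes (1 and 1 adjusted over the list alone), 1 fell of 3 NK genes (1 adjusted over the list alone), 1 rose of 2 gamma-delta genes (1 adjusted over the list alone), and no myeloid gene of 3 and no CD8 gene of 2 passed in edgeR (0 and 1 adjusted over the list alone). At an unadjusted p under 0.05 there was 1 gene in each of the myeloid and CD8 lists, with DESeq2 0 and 1 calls and with limma-voom 0 and 0. The NK list had a median of 0.39 and a mean of -0.28, and the gamma-delta list a median of -0.35 although camera placed it higher.

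Between Tfh and Th17, 2113 of 12591 genes differed, 856 higher and 1257 lower in Tfh, of which 810 by at least 2-fold. In 14.5% of the genes tested the 5 Tfh and 5 Th17 libraries did not overlap, against 0.79% by chance. Among the highest fold changes were those of Khdrbs3 (8.65-fold, 3.11 ± 0.32), Nrep (6.24-fold, 2.64 ± 0.49) and Ephx1 (5.26-fold, 2.40 ± 0.27). Among the lowest, besides Il2, were Cdh17 (47.1-fold, -5.56 ± 0.72, but -8.10 without Tfh replicate 2) and H2-Ab1, of MHC class II (19.7-fold, -4.30 ± 0.45). Calls numbered 3568 with limma-voom, 3310 with a GC correction chosen after seeing the data, and 138 with glmTreat for changes above 2-fold.

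The comparison of Tfh with Th1 cells addresses how far the Tfh cells lie from a lineage that makes interferon gamma. Maf was 153-fold higher in Tfh than in Th1 cells (7.26 ± 0.26, n = 5 per condition, edgeR adjusted p = 1.29e-13) and Bcl6 9.31-fold (3.22 ± 0.30, edgeR adjusted p = 5.40e-08). Tbx21 fell 47.7-fold (-5.58 ± 0.30, edgeR adjusted p = 2.89e-11) and Prdm1 180-fold (-7.49 ± 0.61, edgeR adjusted p = 8.84e-09; -9.36 without Tfh replicate 5). Il17f, nearly silent in Th1 cells at 7.56 ± 6.03 CPM, rose 569-fold (9.15 ± 0.51, edgeR adjusted p = 4.40e-11).

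In the Tfh programme 12 of 20 genes rose, 4 fell and 4 did not pass (12 and 4 adjusted over the list alone), with a median of 2.53 (camera adjusted p = 0.000807). Tox2 rose 563-fold (9.14 ± 0.52; 9.74 without Th1 replicate 5), Pou2af1, which encodes a transcriptional coactivator of B and Tfh cells, 363-fold (8.51 ± 0.31), Angptl2 49.6-fold (5.63 ± 0.30) and Il21 10.2-fold (3.35 ± 0.20). Cd200 fell 14.5-fold (-3.86 ± 0.16), Cd40lg 10.9-fold (-3.45 ± 0.15) and Btla, which encodes an inhibitory receptor, 5.60-fold (-2.49 ± 0.24). In the Th1 programme 22 of 23 genes fell and 1 rose (22 and 1 adjusted over the list alone), with a median of -3.50 (camera adjusted p = 6.70e-10). Gzmb, which encodes granzyme B, fell 278-fold (-8.12 ± 0.55; -9.06 without Tfh replicate 2), Fasl 134-fold (-7.07 ± 0.56; -8.55 without Tfh replicate 4) and the IL-12 receptor gene Il12rb2 113-fold (-6.82 ± 0.29). The gene that rose was Cxcr6, a chemokine receptor gene (100.0-fold, 6.64 ± 0.27). Gata3 rose 3.24-fold (1.70 ± 0.29) and Foxp3 23.7-fold (4.56 ± 0.66; 5.16 without Th1 replicate 3).

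The Th17 programme had 12 of 21 genes rise, 7 fall and 2 not pass (12 and 8 adjusted over the list alone), with a median of 1.54. Its camera adjusted p was 0.0232, with 0.101 at an estimated correlation, 0.0548 with the replicate block and 0.0613 with the GC correction. Ccl20 rose 138-fold (7.11 ± 0.40) and Il1r1 126-fold (6.98 ± 0.20). The cytokine gene Il24, on this list but at 725 ± 51.7 CPM in Th1 cells, fell 3400-fold (-11.73 ± 0.38, or -12.50 without Tfh replicate 5), and Il18r1 fell 14.2-fold (-3.83 ± 0.21). TGF-beta response genes rose in 15 of 21 cases, 2 fell and 4 did not pass (15 and 2 adjusted over the list alone), with a median of 1.71 (camera adjusted p = 1.86e-05). Nt5e, which encodes the ectoenzyme CD73, rose 156-fold (7.29 ± 0.19). Chemokine receptor genes rose in 7 of 13 cases, 2 fell and 4 did not pass (7 and 2 adjusted over the list alone), with a median of 0.73. The camera adjusted p was 0.0264, with 0.0651 at an estimated correlation and 0.0548 with the replicate block. Cx3cr1 rose 92.7-fold (6.53 ± 0.56, or 7.45 without Th1 replicate 3). Naive and lymph-node homing genes rose in 6 of 12 cases, 3 fell and 3 did not pass (6 and 3 adjusted over the list alone), with a median of 0.35. Klf2 rose 53.7-fold (5.75 ± 0.28). The camera adjusted p of this list was 0.0474, and the adjusted p = 0.112 with an estimated correlation. The camera value rose to 0.0520 without Th1 replicate 5 and to 0.0517, 0.0556 and 0.0508 without Tfh replicates 1, 2 and 4. It was 0.0729 with the strict filter, 0.0557 with the replicate block and 0.0632 with the GC correction.

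Several further lists were called lower in Tfh than in Th1 cells. The integrated stress response had 14 of 15 genes fall and 1 not pass (14 adjusted over the list alone), with a median of -2.47 (camera adjusted p = 1.12e-08), and Atf3 fell 181-fold (-7.50 ± 0.57; -9.49 without Tfh replicate 1). Interferon response genes fell in 17 of 24 cases, 3 rose and 4 did not pass (18 and 3 adjusted over the list alone), with a median of -1.51 (camera adjusted p = 1.58e-05), and the GTPase gene Iigp1 fell 52.1-fold (-5.70 ± 0.47). Cytotoxic effector genes fell in 7 of 9 cases and 2 rose (7 and 2 adjusted over the list alone), with a median of -4.30 (camera adjusted p = 0.00409). Cholesterol synthesis genes fell in 13 of 22 cases and 9 did not pass (13 adjusted over the list alone), with a median of -0.94 (camera adjusted p = 6.29e-05), and Fdps fell 5.23-fold (-2.39 ± 0.15). Glycolysis genes fell in 17 of 19 cases, 1 rose and 1 did not pass (17 and 1 adjusted over the list alone), with a median of -1.0 (camera adjusted p = 1.99e-05, and adjusted p = 0.109 with an estimated correlation), and Hk2 fell 8.05-fold (-3.01 ± 0.18). Proliferation genes fell in 17 of 24 cases, 3 rose and 4 did not pass (17 and 3 adjusted over the list alone), with a median of -0.67 (camera adjusted p = 0.00463, and adjusted p = 0.278 with an estimated correlation), and the kinase gene Aurka fell 2.97-fold (-1.57 ± 0.21). IL-2 and STAT5 response genes fell in 11 of 15 cases, 1 rose and 3 did not pass (11 and 1 adjusted over the list alone), with a median of -1.70 (camera adjusted p = 2.56e-05, and adjusted p = 0.0505 with an estimated correlation).

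Other lists were not called between Tfh and Th1. Among 23 cytokine genes 8 rose and 11 fell (9 and 11 adjusted over the list alone), and Il3, with 1 count in Tfh against 7069 in Th1, was lower by a ratio of 4960 (95% interval 890 to 196000), the count being in Tfh replicate 5. AP-1, NFAT and NR4A factors rose in 7 and fell in 5 of 18 cases (8 and 5 adjusted over the list alone), and Batf3 fell 1230-fold (-10.26 ± 0.46). STAT3 response genes rose in 7 and fell in 3 of 15 cases (8 and 3 adjusted over the list alone), with a camera adjusted p of 0.0542. That list passed without any of 8 single libraries: adjusted p = 0.0328 and 0.0294 without Th1 replicates 3 and 4, 0.0488, 0.0453 and 0.0488 without Th17 replicates 1, 3 and 5, and 0.0380, 0.0461 and 0.0414 without Tfh replicates 2, 3 and 5. It also passed with RLE factors (0.0492), library size only (0.0483), no filter on low counts (0.0174) and without the 5 libraries of steepest GC trend (0.0324). Treg genes had 5 rise and 7 fall of 14 (5 and 7 adjusted over the list alone), with a median of -0.65 but a mean of 0.13, and Ebi3 fell 32.9-fold (-5.04 ± 0.63). Th2 genes had 2 rise and 2 fall of 8 (2 and 2 adjusted over the list alone), and Ccr8 rose 9.81-fold (3.29 ± 0.30). Co-inhibitory receptors had 1 rise and 4 fall of 9 (1 and 4 adjusted over the list alone), heat shock genes 1 and 4 of 8 (1 and 4 adjusted over the list alone), and p53 response genes 2 and 6 of 10 (2 and 6 adjusted over the list alone), among them Cdkn1a, a cell cycle inhibitor gene, which fell 15.9-fold (-4.0 ± 0.20). Of the 8 mitochondrially encoded genes, 0 passed in edgeR (0 adjusted over the list alone, 0 at an unadjusted p under 0.05) and 0 in DESeq2, while 2 passed in limma-voom.

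Markers of other cells were also tested between Tfh and Th1. Of 3 B cell genes tested, 2 fell (2 adjusted over the list alone; camera adjusted p = 0.0184, adjusted p = 0.0718 with an estimated correlation, 0.0574 without a filter on low counts, 0.173 with the strict filter and 0.0534 without the 5 libraries of steepest GC trend), and Ebf1 was at 17.4 ± 4.53 CPM in Th1. Myeloid genes fell in 2 of 3 cases (2 adjusted over the list alone), CD8 genes in 1 of 2 (2 adjusted over the list alone) and gamma-delta genes in 2 of 2 (2 adjusted over the list alone). Of 2 gamma chain genes that the gamma-delta list missed, Trgc1 went the other way, higher in Tfh than in Th1, while Trgc2 fell. NK genes had 1 rise and 1 fall of 3 (1 and 1 adjusted over the list alone), with a median of -0.71 but a mean of 0.51. Klrb1f rose 70.2-fold (6.13 ± 0.59, or 7.34 without Th1 replicate 2) and Cd68 was at 10.7 ± 4.91 CPM in Th1. The camera adjusted p was 0.0554 for the myeloid list, and it fell to 0.0420 without Th1 replicate 1 and 0.0436 without Th17 replicate 3, 0.0499 with library size only and 0.0490 with the GC correction. The gamma-delta list also had 0.0554, with 0.0175 without Th17 replicate 2 and 0.0178, 0.0170 and 0.0165 without Tfh replicates 2, 3 and 5, and 0.0483 with library size only.

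Between Tfh and Th1, 6206 of 12591 genes differed, 3037 higher and 3169 lower in Tfh, of which 3484 by at least 2-fold. In 34.3% of genes the libraries did not overlap, against 0.79% by chance. Several of the largest changes were lower bounds. Cysrt1 was at least 671-fold higher in Tfh (30.3 ± 9.41 CPM against no count), Rasgrp3 at least 371-fold, Ntng1 at least 358-fold and Gja5, a connexin gene, at least 277-fold. Sema3b, a semaphorin gene, was at least 1240-fold lower (80.5 ± 8.73 CPM in Th1 against no count), and the metallothionein gene Mt3 at least 748-fold. With glmTreat for changes above 2-fold, 1971 genes differed.

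The comparison of Th17 with Th1 cells addresses how the Th17 lineage differs from the same Th1 libraries. Maf was 74.8-fold higher in Th17 than in Th1 cells (6.22 ± 0.25, n = 5 per condition, edgeR adjusted p = 8.55e-13) and Bcl6 4.41-fold (2.14 ± 0.29, edgeR adjusted p = 9.30e-06). Tbx21 fell 70.7-fold (-6.14 ± 0.31, edgeR adjusted p = 1.91e-11) and Prdm1 43.3-fold (-5.44 ± 0.50, edgeR adjusted p = 6.93e-08). Il17f rose 1440-fold (10.50 ± 0.53, edgeR adjusted p = 2.27e-11). Gata3 did not pass (-0.14 ± 0.29), and Foxp3 rose 13.0-fold (3.71 ± 0.65, or 4.30 without Th1 replicate 3).

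In the Th17 programme 13 of 21 genes rose, 5 fell and 3 did not pass (14 and 5 adjusted over the list alone), with a median of 2.19 (camera adjusted p = 0.000157). Ccl20 rose 630-fold (9.30 ± 0.43) and Tmem176a 119-fold (6.90 ± 0.47), while Il24 fell 140-fold (-7.13 ± 0.28) and Il18r1 17.8-fold (-4.16 ± 0.21). The Tfh programme had 12 of 20 genes rise, 5 fall and 3 not pass (12 and 5 adjusted over the list alone), with a median of 1.62 (camera adjusted p = 0.00560). Pou2af1 rose 210-fold (7.72 ± 0.30), Tox2 181-fold (7.50 ± 0.52; 8.09 without Th1 replicate 5) and Il21 9.61-fold (3.27 ± 0.19), while Btla fell 8.08-fold (-3.01 ± 0.24). Th1 programme genes fell in 19 of 23 cases, 1 rose and 3 did not pass (19 and 1 adjusted over the list alone), with a median of -2.42 (camera adjusted p = 3.96e-09). Gzmb fell 680-fold (-9.41 ± 0.60) and Nkg7 104-fold (-6.70 ± 0.43), and Cxcr6 rose 124-fold (6.96 ± 0.27). Il2 rose 20.2-fold from 2.10 ± 1.16 CPM in Th1 (4.34 ± 0.44).

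TGF-beta response genes rose in 15 of 21 cases, 1 fell and 5 did not pass (16 and 2 adjusted over the list alone), with a median of 1.10 (camera adjusted p = 8.42e-07). Tgfbi rose 477-fold (8.90 ± 0.62; 10.15 without Th1 replicate 5) and Nt5e 89.0-fold (6.48 ± 0.18). Chemokine receptor genes rose in 8 of 13 cases, 1 fell and 4 did not pass (9 and 1 adjusted over the list alone), with a median of 1.88 (camera adjusted p = 0.000443), among them Ccr6, the receptor of CCL20 (12.9-fold, 3.69 ± 0.26). The integrated stress response had 14 of 15 genes fall and 1 not pass (14 adjusted over the list alone), with a median of -1.88 (camera adjusted p = 1.02e-09), and Atf3 fell 42.1-fold (-5.39 ± 0.47). Interferon response genes fell in 18 of 24 cases, 1 rose and 5 did not pass (18 and 2 adjusted over the list alone), with a median of -1.04 (camera adjusted p = 5.62e-07), and Iigp1 fell 25.1-fold (-4.65 ± 0.43). Cytotoxic effector genes fell in 7 of 9 cases and 2 rose (7 and 2 adjusted over the list alone), with a median of -4.14 (camera adjusted p = 0.00162). Co-inhibitory receptor genes fell in 5 of 9 cases, 2 rose and 2 did not pass (6 and 2 adjusted over the list alone), with a median of -1.18 (camera adjusted p = 0.0134), and Cd274, which encodes PD-L1, fell 6.56-fold (-2.71 ± 0.19).

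With an estimated correlation, 4 further calls between Th17 and Th1 were lost. IL-2 and STAT5 response genes fell in 10 of 15 cases, 2 rose and 3 did not pass (10 and 2 adjusted over the list alone), with a median of -0.81 (camera adjusted p = 0.00560, and adjusted p = 0.162 with an estimated correlation). Proliferation genes rose in 10 of 24 cases and 14 did not pass (10 adjusted over the list alone), with a median of 0.31 (camera adjusted p = 0.0203, and adjusted p = 0.406 with an estimated correlation). The replication gene Mcm3 rose 2.14-fold (1.10 ± 0.14). The p53 response genes fell in 6 of 10 cases, 2 rose and 2 did not pass (7 and 2 adjusted over the list alone), with a median of -0.88 (camera adjusted p = 0.0325, adjusted p = 0.0914 with an estimated correlation, and 0.163 with the strict filter), and Cdkn1a fell 5.4-fold (-2.43 ± 0.19). STAT3 response genes rose in 8 of 15 cases, 3 fell and 4 did not pass (8 and 3 adjusted over the list alone), with a median of 0.42 (camera adjusted p = 0.0351, and adjusted p = 0.329 with an estimated correlation). The STAT3 call was also lost without Th1 replicate 1 (adjusted p = 0.0678), Th1 replicate 2 (0.0529) and Th17 replicate 4 (0.0603), and with the strict filter (0.0512).

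Other lists were not called between Th17 and Th1. Cytokine genes had 11 rise and 9 fall of 23 (11 and 9 adjusted over the list alone), glycolysis genes 4 and 4 of 19 (5 and 5 adjusted over the list alone), and cholesterol synthesis genes 3 and 8 of 22 (4 and 8 adjusted over the list alone). AP-1, NFAT and NR4A factors had 7 rise and 5 fall of 18 (7 and 5 adjusted over the list alone), with a median of 0.33 but a mean of -0.37, and Batf3 fell 93.1-fold (-6.54 ± 0.33). Treg genes had 6 rise and 6 fall of 14 (6 and 6 adjusted over the list alone), with a median of -0.54 but a mean of 0.03. Th2 genes had 2 and 2 of 8 (3 and 2 adjusted over the list alone), naive and lymph-node homing genes 5 and 3 of 12 (6 and 3 adjusted over the list alone), and heat shock genes 3 and 2 of 8 (4 and 2 adjusted over the list alone). Klf2 rose 14.1-fold (3.82 ± 0.26). Among 8 mitochondrially encoded genes, 0 passed in edgeR (0 adjusted over the list alone, 2 at an unadjusted p under 0.05) and 0 in DESeq2, while 2 passed in limma-voom. Among markers of other cells, all 3 B cell genes fell (3 adjusted over the list alone; camera adjusted p = 0.00161), including Ighm (1.88-fold, -0.91 ± 0.21). Both gamma-delta genes tested fell (2 adjusted over the list alone; camera adjusted p = 0.00903), including Trdc (4.95-fold, -2.31 ± 0.28). The list missed the gamma chain genes named Trgc1 and Trgc2. Trgc1 went the other way, higher in Th17 than in Th1, while Trgc2 fell. Without Th1 replicates 2, 3, 4 or 5 the gamma-delta list had an adjusted p of 0.144, 0.148, 0.140 or 0.148. Myeloid genes fell in 2 of 3 cases (2 adjusted over the list alone) at a camera adjusted p of 0.0505, which was 0.0372, 0.0443, 0.0383 and 0.0447 without Th1 replicates 1 and 5 and Th17 replicates 3 and 5, 0.0457 with library size only and 0.0464 with the GC correction. CD8 genes fell in 1 of 2 cases (1 adjusted over the list alone), and NK genes had 1 rise and 1 fall of 3 (2 and 1 adjusted over the list alone).

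Between Th17 and Th1, 4642 of 12591 genes differed, 2397 higher and 2245 lower in Th17, of which 2401 by at least 2-fold. In 28.8% of genes the libraries did not overlap, against 0.79% by chance. The largest changes again included lower bounds, with Gja5 at least 838-fold higher in Th17 (39.8 ± 7.02 CPM against no count), Cysrt1 at least 490-fold and Ppp1r14c at least 394-fold. Dnah7a and Dnah3, both dynein genes, were at least 374-fold and at least 258-fold lower. With glmTreat for changes above 2-fold, 1326 genes differed.

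Tfh and Th17 cells departed from Th1 cells in largely common genes. Maf, Bcl6, Il21, Pou2af1 and Nt5e rose in both comparisons, and Tbx21, Prdm1, Gzmb, Batf3 and Atf3 fell in both. In the same direction 3868 genes were called in both, 1960 higher and 1908 lower than in Th1, which were 62.3% of the Tfh calls and 83.3% of the Th17 calls, and 28 were called in opposite directions. Il2 was one of these, 20.2-fold higher in Th17 and lower in Tfh (0.338 ± 0.472 CPM against 2.10 ± 1.16 in Th1). Independent lists of these sizes would share 1143 genes, 578 higher and 565 lower. Since both comparisons use the same Th1 libraries, all 15 libraries, the Th1 ones included, were simulated 20 times from the Th1 means. The highest count of shared calls was 0. With no gene changed, few calls could arise, so that 0 is no measure for the 3868. The median correlation of log2 fold changes was 0.488, against 0.906 observed across genes. The covariance was 2.485 against 0.068 simulated, a difference of 2.417. With the Th1 libraries split between the comparisons in 20 ways, the median number of shared calls was 2764 (2526 to 2996), with at most 165 in opposite directions, 664 for independent lists, a correlation of 0.865 and a covariance of 2.493.

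A gene was set apart in a condition when it differed from both others in the same direction. Tfh cells were set apart by 1625 genes (666 higher and 959 lower), Th17 cells by 366 (229 higher and 137 lower) and Th1 cells by 3868 (1908 higher and 1960 lower). The Th1 genes are by definition the calls shared by Tfh and Th17 against Th1, so they are no second result. The counts of the conditions sum to 5859 but are 4946 distinct genes. Of these, 913 were set apart in 2 conditions, such as Il17a, higher in Th17 and lower in Th1. Higher in Tfh than in both others were Khdrbs3, Nrep and Cx3cr1, with 39.2 ± 6.72, 11.4 ± 8.31 and 19.8 ± 5.62 CPM in Tfh. Lower in Tfh were H2-Ab1, Igfbp7 and Mt2, the last a metallothionein gene at 7.13 ± 0.992 CPM in Tfh against 125 ± 34.2 in Th17 and 127 ± 31.4 in Th1. Higher in Th17 were Il2, Il17a, Dab2 (22.5 ± 2.73 CPM in Th17 and 2.06 ± 1.17 in Tfh) and Ngfr (18.2 ± 11.3 and 2.0 ± 0.989 CPM), each with 5 counts or fewer in Th1 except Il2. Lower in Th17 were Rasgrp4, Tnfsf10, Entpd1 and Arl5c, at 6.05 ± 1.90, 4.48 ± 2.30, 4.45 ± 1.52 and 5.05 ± 1.09 CPM. Higher in Th1 were Sema3b, Ifng, Il3 and Mmp7, an extracellular protease gene (11.5 ± 4.40 CPM in Th1 against no count in Tfh and Th17). Lower in Th1 were Cysrt1, Gja5 and Rasgrp3, without a count there, and Daw1 (0.0533 ± 0.0489 CPM in Th1 and 63.6 ± 14.6 in Tfh). Of the Th17 genes, 772 were set apart with limma-voom and 685 with the GC correction chosen after seeing the data, and of the Tfh genes 2555 and 2489.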

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

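The tests of the 3 patterns weighed here were chosen only after the results were seen. A library was singled out when it lay far from the other 4 of its condition by Dixon's test, which chance gives in about 1 of 20 groups. This happened for 4 of 30 library measures (1.5 by chance) and 16 of 252 gene levels (12.6 by chance), so the number of gene levels was close to that of chance.

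Th1 replicate 3 had a total of 25.2 M counts (others 7.34 to 11.48). Tfh replicate 1 had 3.27% of its counts on unnamed IDs (others 1.49 to 1.89). It lay at 81.4 on the first principal component (others 62.6 to 67) and at 94 on the second (others -1 to 12.1). In CPM, Tfh replicate 1 also differed in Ccne2 (1.16, others 14 to 18.8), Nt5e (983, others 1380 to 1490), Pou2af1 (344, others 421 to 441) and Tmem176a (10.2, others 45.8 to 57.7). Tfh replicate 2 differed in Btla (257, others 117 to 155) and Sesn1 (123, others 85 to 94.4). Tnfsf10 in Tfh replicate 3 was at 17.1 CPM (others 12 to 13.1), Lag3 in Tfh replicate 4 at 658 (others 400 to 459), and Gpr83 in Tfh replicate 5 at 7.61 (others 17 to 18.8). Among Th17 libraries, replicate 1 differed in Ccr6 (93.4, others 68.3 to 74.6) and Il2 (59.8, others 34.8 to 41.4), replicate 2 in Cdh17 (22, others 6.45 to 8.86) and Klf2 (32, others 22.8 to 24.1), and replicate 4 in Cdkn1a (130, others 80 to 89). Among Th1 libraries, Fasl in replicate 2 was at 65.9 CPM (others 54 to 57.2) and Mmp7 in replicate 1 at 19.1 (others 7.66 to 10.4).

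Tfh cells were sorted as IL-17A negative, yet their Il17f was at 39.4% of the Th17 level. If cells of the Th17 sort had been carried over, each of their transcripts would reach at least the carried share. Of 3 genes on which the gate did not act directly, only 1, Il2 at 0.785%, lay below Il17f by more than 2 standard errors (8.55). Ccl20 at 21.9% (1.84) and Il23r at 23.3% (1.57) did not. The bound asked for 2 genes and had been lowered from all genes tested after the values were seen, so by that bound carry-over stays open. Il17a at 6.8% decides nothing because the gate acted on it. Yet if each transcript reaches at least the carried share, Il2 limits that share to about 0.785%. The 3 metallothionein genes also fell in Tfh against Th17, by a median of 17.5-fold. These values, weighed after they were seen, argue against carried cells of mean Th17 levels as the source of the whole Il17f level. A smaller part from carried cells stays open. Reads of Il17a counted as Il17f are argued against by a ratio of Il17f to Il17a of at least 232 in each Tfh library. Cells that make Il17f without the Il17a reporter could also give this pattern, and no biological explanation was tested.

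Ngfr followed Il17a across conditions, with 974 counts in Th17, 87 in Tfh and 1 in Th1. The altered Il17a allele, by its published design, carries a human NGFR sequence, so reads of that reporter may be counted as mouse Ngfr. The log2 fold change of Ngfr between Tfh and Th17 differed from that of Il17a by 0.68 ± 0.56 (1.22 standard errors), which fits that reading without excluding transcription of Ngfr itself. With the GC trend removed, Ngfr still differed at an edgeR adjusted p of 2.93e-06, which argues against GC bias. Levels ran from 4.55 to 34.4 CPM among Th17 and from 0.565 to 3.29 CPM among Tfh libraries.

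Libraries of 1 condition differed along a common gradient, which held 67.7% of the variance within conditions over 5616 genes. With the trend in GC content removed, 34.7% of the gradient's variance was left, and with the trend in transcript length removed, 96.2%, which argues against length. The gradient also followed the total count, centred in each condition (Spearman's rho 0.68, permutation adjusted p = 0.00664, and 0.63 without Th1 replicate 3 and Tfh replicate 1). GC content and depth thus both remain open as likely technical sources. The gradient also partly followed the replicate number. On the leading component over all genes tested, replicate 4 scored 38.2, 39.1 and 38.9 in Th1, Th17 and Tfh. Replicate 1 scored -60.8, -27.4 and -39.1, and replicate 2 scored -5.2, -24.6 and -13.1. Replicates 3 (41.8, -1.3 and 5.3) and 5 (-14, 14.3 and 8) were mixed in sign. A fit with the replicate number as a block gave more calls in each comparison. This fits some spread shared by number, which the main fit leaves in its error. What the number marks is not given, so the source of that spread was not tested and stays open. No biological explanation was tested, as the labels give none.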

How the results depend on the processing

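Tests with the GC correction were chosen only after the results were seen. Of 279 counts under alternatives, 263 stayed within the bound set for a change. Among 1932 list values and 5790 gene values, 0 reversed direction where the main fit or the alternative gave a call. Changes of sign without a call in either were not counted, and most genes were named because they had passed. Of the list values 50 lost and 46 gained a call, and of the gene values 54 and 6. Calls between Tfh and Th17 became 3568 with limma-voom, 3310 with the GC correction, 3906 with that and the replicate block, and 138 with glmTreat, which asks for more than 2-fold and so gave 1971 for Tfh against Th1 and 1326 for Th17 against Th1. Genes set apart became 2555 (Tfh) and 772 (Th17) with limma-voom, 2489 and 685 with the GC correction, 2909 and 872 (8904 summed over conditions) with that and the block, and 584 (Th17) with the block alone. Lists called between Tfh and Th1 became 7 with an estimated correlation. Fry, which asks another question (whether a list changed at all, not against other genes), called 24. Apart from glmTreat and fry, the cause was not tested. Leaving out 1 library gave 5727 to 6344 calls (Tfh against Th1), 1613 to 2393 (Tfh against Th17) and 4096 to 5055 (Th17 against Th1). Shared calls, which are the genes set apart in Th1, ranged over 3460 to 4115. Sums over conditions of genes set apart were 5053 to 6250 (Tfh 1295 to 1800, Th17 245 to 419). Lists called ranged over 13 to 16, 11 to 12 and 13 to 16. With the condition means removed from log2 CPM, same-numbered libraries of different conditions correlated at -0.1 to 0.57. The values were highest for number 4 (0.44, 0.46 and 0.57), and not each library was best with its own number. The block gave 6923 (Tfh against Th1), 2941 (Tfh against Th17) and 5487 (Th17 against Th1) calls, against 6206, 2113 and 4642 in the main fit. It ended the camera calls of the Th17 (0.0548), chemokine receptor (0.0548) and naive (0.0557) lists for Tfh against Th1. For Tfh against Th17 it ended that of the TGF-beta list (0.0545). Depth limits genes of low count, such as Prdm1 in Tfh with 6 counts.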

Other observations

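The gene families in this part, for which no test of the family as a group was run, and the test of the shared direction were chosen only after the results were seen, whereas the tests of groupings were planned before. Metallothioneins, which bind zinc and copper, were low in Tfh cells: all 3 tested fell against Th1 (median -4.15) and against Th17 (median -4.13). Mt1 was at 34.4 ± 7.77 CPM in Tfh, 461 ± 94.1 in Th17 and 373 ± 103 in Th1 (SD, n = 5). The interferon-induced transmembrane genes fell in all 3 comparisons, 3 of 3 each, with medians of -7.34 (Tfh against Th1), -3.40 (Tfh against Th17) and -4.46 (Th17 against Th1). Ifitm3 went from 341 ± 84 CPM in Th1 to 7.71 ± 2.54 in Th17 and 0.451 ± 0.494 in Tfh.

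Of 84 ribosomal protein genes, 53 fell and 1 rose in Tfh against Th1 (median -0.66), and 35 fell and 1 rose in Th17 against Th1 (median -0.54, 30 and 1 with library size only), while 2 fell between Tfh and Th17. Rplp0 was at 4030 ± 574 CPM in Tfh and 6280 ± 1670 in Th1. Of 21 histone genes, 11 rose and 1 fell in Tfh against Th1 (median 1.29), and 12 rose in Th17 against Th1 (median 1.57), such as H1f0 (1.35 ± 0.12). Gimap genes, which encode GTPases of lymphocyte survival, rose in 5 of 8 cases in Tfh against Th17 (median 0.68), among them Gimap3 (0.94 ± 0.17), while 4 fell and 1 rose in Th17 against Th1 (median -0.38) and 4 rose and 2 fell in Tfh against Th1 (median 0.46). Of 38 proteasome genes, 15 rose and 2 fell in Th17 against Th1 (median 0.22) 6 fell in Tfh against Th17 (median -0.25), and 7 rose and 7 fell in Tfh against Th1 (median 0.01, or -0.03 with RLE factors).

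An unnamed gene, ID 100861531, took 2.491% of the counts of Tfh replicate 1, against 0.522% to 1.585% in the other libraries.

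Other groupings of the same libraries were set beside the real one. Mixing conditions puts their differences into the spread within groups, which lowers the gene counts. These groupings therefore cannot show how many calls unchanged groups would give. For Tfh against Th1, 1 of 100 splits, the real one, gave as many genes (6206, highest other 213) and 1 as many lists (14, highest other 11). For Tfh against Th17, 1 of 100 gave as many genes (2113, highest other 2), but 2 as many lists (12 and 12). For Th17 against Th1, 1 of 100 gave as many genes (4642, highest other 1219) and 1 as many lists (15, highest other 13). Among 100 regroupings of all 15, 1 gave as high a sum over conditions of genes set apart (5859, highest other 3860) and 1 as many shared calls (3868, highest other 3860). These 2 counts are not separate results, since the sum contains the shared calls as the genes set apart in Th1. The regrouping with 3860 kept the 5 Th1 libraries together and mixed Th17 with Tfh, so it points to the distance of Th1 from the others.

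Tfh libraries lay further from Th1 than Th17 libraries did, so Tfh might differ from Th17 partly along the direction in which Th17 differs from Th1. With the Th17 libraries split between the comparisons in 20 ways, the log2 fold changes correlated across genes at a median of 0.154 (0.086 to 0.193), and 73.4% of genes called in both had the same sign. With the GC correction these values were 0.151 and 69.6%. The correlation was weak, but it covers all genes tested, also those that did not differ, whose noise lowers it. It therefore does not measure the size of the shared part, which was not estimated.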
